A study of Saccharomyces cerevisiae with 44 samples.

How the data were processed

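The study measured RNA in Saccharomyces cerevisiae of strain W303 by sequencing. Newly made RNA, here called nascent RNA, was read by 4tU-seq, which sequences RNA that took up 4-thiouracil. Total RNA, here called steady-state RNA, was read by RNA-seq. The 44 samples form 22 groups of 2 replicates. Quiescent cells were grown for 7 or 8 days in rich medium with 2% glucose and purified on a gradient. G1 cells were arrested with alpha factor at 5 µg/ml, with a second dose at 90 minutes where needed. Cells around the diauxic shift, the time at which glucose runs out, were taken 2 h before it and 2 h, 24 h and 48 h after it. The strains were wild-type, rrp6Δ, which lacks the nuclear exosome nuclease Rrp6, Nab3-AID, in which auxin triggers loss of the termination factor Nab3, and OsTIR-AID, the control for auxin. Auxin (IAA) was added at 1 mg/ml. The design text speaks of biological replicates. The labels do not say that replicates are independent cultures, but the strain numbers of the replicates differ.

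The authors deposited tables of counts, one column per sequencing run and one line per gene or transcript. According to the submitters' processing notes, read quality was assessed with FastQC and MultiQC, molecular identifiers were handled with UMI-tools, reads were aligned with STAR to a joined genome holding S. cerevisiae sacCer3/R64, Kluyveromyces lactis and the 20S RNA replicon, files were handled with SAMtools, counts were made with HTSeq and coverage tracks with deepTools. Versions of these tools were not given in the sources used here. HTSeq left out reads that aligned to more than 1 place, so counts shared by near-identical copies of a gene are uncertain. The mRNA table held 11677 lines, of which 6600 were S. cerevisiae genes and 5076 K. lactis genes, and there was a second table of the same size for the opposite strand. The table of noncoding RNAs held 4318 representative transcripts, merged by the authors from catalogues of cryptic unstable transcripts (CUT, CUTHMM, CUT4x), stable unannotated transcripts (SUT), Xrn1-sensitive transcripts (XUT), Nrd1-unterminated transcripts (NUT) and Ssu72-restricted transcripts (SRAT). The version before merging held 8412. A table of coding and structural features held 7006 lines, and tables of transcripts assembled from the nascent reads held 5208 for G1 and 6451 for quiescence. Of the S. cerevisiae locus tags 5917 were matched to the reference table of symbols, and 5295 had a standard name.

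Each table had 46 columns for the 44 samples, because wild-type 48 h replicate 1 and rrp6Δ quiescent steady-state replicate 2 were sequenced in both batches. The columns of one sample were summed. Aligned reads per sample ranged from 8394823 to 68400863. Reads counted on S. cerevisiae mRNAs ranged from 1337088 to 11939647 and reads counted on noncoding RNAs from 642444 to 2693226. The share of reads left out as not unique ranged from 7.99% to 62.5%, that without a feature from 6.36% to 28.0%, and that of ambiguous reads from 0.121% to 1.99%. Between the replicates of a group the chi-square per gene of the counts, over genes with at least 20 reads, ranged from 2.26 to 87.2, and between the 2 runs of the same sample it was 0.767 and 5.18.

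Separate fits were made with edgeR 4.0.16 in R 4.3.3 for the 8 wild-type libraries made with the Ovation SoLo kit, for the 8 libraries of quiescent rrp6Δ and wild-type cells at day 8, for the 20 RNA-seq libraries of G1 and the diauxic shift, and for the 8 libraries with auxin. The last 3 sets were made with the Universal Plus kit. No comparison crossed the kits. Libraries were scaled by TMM on S. cerevisiae genes, and noncoding RNAs took the library sizes and factors of the mRNA table. Low counts were removed with filterByExpr. Changes were tested with the robust quasi-likelihood F-test, and p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Every p of a gene or noncoding RNA in the text is from edgeR unless another test is named. A gene is called changed, higher or lower when it passed this threshold. Values are log2 fold changes with a standard error, which is the size of the change over the square root of F. Log2 CPM, the counts scaled to library size, used a prior count of 2. There were 26 comparisons, 15 of mRNAs and 11 of noncoding RNAs, and 2 of the mRNA comparisons tested an interaction. Read ratios per library were compared by exact permutation, two-sided. With 2 against 2 samples the smallest p that this test can give is 0.333. Shared calls were compared by Fisher's exact test, two-sided. Reads are not independent molecules, and the intervals at 95% and the floors of 3 counts over a group cover counting error only.

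The following 23 gene lists were fixed before the data were examined: ribosomal protein genes, ribosome biogenesis, glycolysis, gluconeogenesis and glyoxylate cycle, TCA cycle, respiratory chain and ATP synthase, fatty acid beta-oxidation and peroxisome, heat shock and chaperones, trehalose and glycogen metabolism, stationary-phase genes, autophagy, proteasome, pheromone response, core histones, mitosis and G2/M, S phase and G1/S, meiosis, nuclear exosome with its cofactors and Nrd1-Nab3-Sen1, cytoplasmic mRNA decay, genes reported to be attenuated by Nrd1-Nab3-Sen1, phosphate regulon, iron regulon, and mitochondrial ribosome. Lists were tested against all other genes with camera in limma 3.58.1, with the preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 23 lists of a comparison. Members called changed were counted over all genes and again with p adjusted over the list alone. All lists are given for quiescence against G1 in steady-state RNA, and for the other comparisons the text describes a few with small camera p or with a tie to the question asked.

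Genes were named by a fixed rule. They had a standard name, were called, had replicates of the 2 groups that did not overlap, and had a mean log2 CPM of at least 3 for mRNAs and 1 for noncoding RNAs. The text draws on the 5 largest rises and 5 largest falls of each comparison and on up to 4 members of each list described. RRP6, NAB3, NRD1, SEN1, IMD2, PHO84, SER3, URA2, FUS1, SNZ1, HSP12 and HSP26 were followed throughout as genes with a known tie to the exosome, to Nrd1-Nab3-Sen1, to mating or to quiescence. Where a group had 0 counts a change is given as at least the fold that a floor of 3 counts allows. Where it had 1 to 3 counts the ratio of the counts is given with its 95% interval.

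The wild-type libraries of quiescence and G1 share strains, as do the wild-type times around the shift. The differences between replicates correlated across genes at -0.029 to 0.432 with a median of 0.12 in 6 pairs of groups of the Ovation set, and at -0.054 to 0.027 with a median of -0.013 in 6 pairs of wild-type times, where genes are not independent replicates. With the replicate as a block, the count of mRNAs called between quiescence and G1 was 4513 in steady-state RNA, 3808 in nascent RNA and 2392 in the interaction. It was 4786 for wild-type cells 2 h after the shift and 5215 at 48 h. For noncoding RNAs it was 2067 in steady-state and 2447 in nascent RNA.

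The fits were tested on simulated data with 200 changed genes per comparison, 100 by 2-fold and 100 by 4-fold. The share recovered for 2-fold and 4-fold changes was 52% and 94% for quiescence against G1 in steady-state RNA, 63% and 96% in nascent RNA, and 16% and 84% for the difference of nascent and steady-state change. It was 42% and 90% for rrp6Δ in quiescent steady-state RNA, 65% and 99% in nascent RNA, and 89% and 95% in G1. At 2 h before the shift it was 97% and 95%, at 2 h after 87% and 96%, at 24 h 89% and 97%, and at 48 h 82% and 94%. Wild-type cells 2 h after the shift gave 94% and 99%, those at 48 h 83% and 98%, and the interaction of the deletion with time 85% and 93%. Nab3 depletion gave 79% and 92% in steady-state and 93% and 98% in nascent RNA. For noncoding RNAs the shares were 10% and 64% for quiescence against G1 in steady-state RNA, 15% and 86% in nascent RNA, 18% and 64% for rrp6Δ in quiescent steady-state RNA, and 53% and 95% in nascent RNA. They were 63% and 85% for rrp6Δ in G1, and 69% and 84%, 62% and 87%, 62% and 89%, and 45% and 82% in the order of the times around the shift. For Nab3 depletion they were 39% and 84% in steady-state and 82% and 99% in nascent RNA. Of the genes called in a simulation, 0.98% to 8.33% had no change. In the day 8 fit the chi-square per gene was 87.2 in nascent and 6.01 in steady-state wild-type RNA. With groups so uneven these shares may not hold.

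Alternatives tried were scaling to K. lactis reads, which were in all libraries, size factors of DESeq2 in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, a replicate block, only the compared groups in the fit, only the first sequencing run, the noncoding table before merging, library sizes of the noncoding table, noncoding RNAs with no coding gene on the same strand, calls of at least 2-fold, reads of both strands, and leaving out 1 library at a time. After the data had been seen, fits without the rrp6Δ libraries of 2 h and 24 h, fits with the labels of those libraries exchanged, and a fit with batch as a term were added. Tables and figures were made with R and Python 3.11.15.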

Results

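RNA of budding yeast was sequenced in growth, at the diauxic shift and in quiescence, a lasting resting state that cells enter after glucose runs out. The series asks how the newly made transcriptome changes in quiescence, and what the nuclear exosome nuclease Rrp6 and the termination factor Nab3 do to it. There were 22 groups of 2 samples: wild-type quiescent and G1 cells in nascent and steady-state RNA (8 libraries), quiescent rrp6Δ and wild-type cells of day 8 in both fractions (8), rrp6Δ and wild-type cells in G1 and at 4 times around the shift in steady-state RNA (20), and quiescent Nab3-AID and OsTIR-AID control cells with auxin in both fractions (8). Values below are log2 fold changes ± standard error with n = 2 samples per group, by edgeR, with positions on the sacCer3/R64 build. For every gene named as one of the largest changes, the values of both samples of a group lay outside the range of the other group.

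RRP6 mRNA was low in the deleted strain throughout, with log2 CPM of 1.83 to 4.35 in the 14 rrp6Δ libraries against 6.32 to 8.09 in the 30 others. Loss of Nab3 acts on the protein, which was not measured. NAB3 mRNA stood at 9.20 in Nab3-AID and 9.72 in control steady-state libraries.

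K. lactis reads came with every library, but the labels do not give the amount of K. lactis material, its basis (cells or RNA mass) or the step at which it was added. Wild-type nascent libraries held 1.39 ± 0.493 S. cerevisiae reads per K. lactis read in quiescence and 36.6 ± 16.9 in G1 (SD, n = 2, exact permutation p = 0.333), a 25.7-fold difference of geometric means. The steady-state libraries of the same states held 8.11 ± 2.31 and 12.98 ± 4.43, a 1.59-fold difference (exact permutation p = 0.333). In wild-type cells the ratio went from 13.8 at 2 h before the shift to 6.89, 2.77 and 1.14 at 2 h, 24 h and 48 h after it. Quiescent rrp6Δ and wild-type cells had 1.92 ± 0.593 and 1.88 ± 0.0519 in nascent RNA (exact permutation p = 1), and 8.89 ± 1.28 and 4.97 ± 0.305 in steady-state RNA. Nab3-AID and control cells had 8.12 ± 1.8 and 4.55 ± 0.0974 in steady-state RNA, and 0.663 ± 0.169 and 0.418 ± 0.131 in nascent RNA. The main values below are shares of all mRNA, and the effect of K. lactis scaling is given with each comparison.

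**Figure D1:**
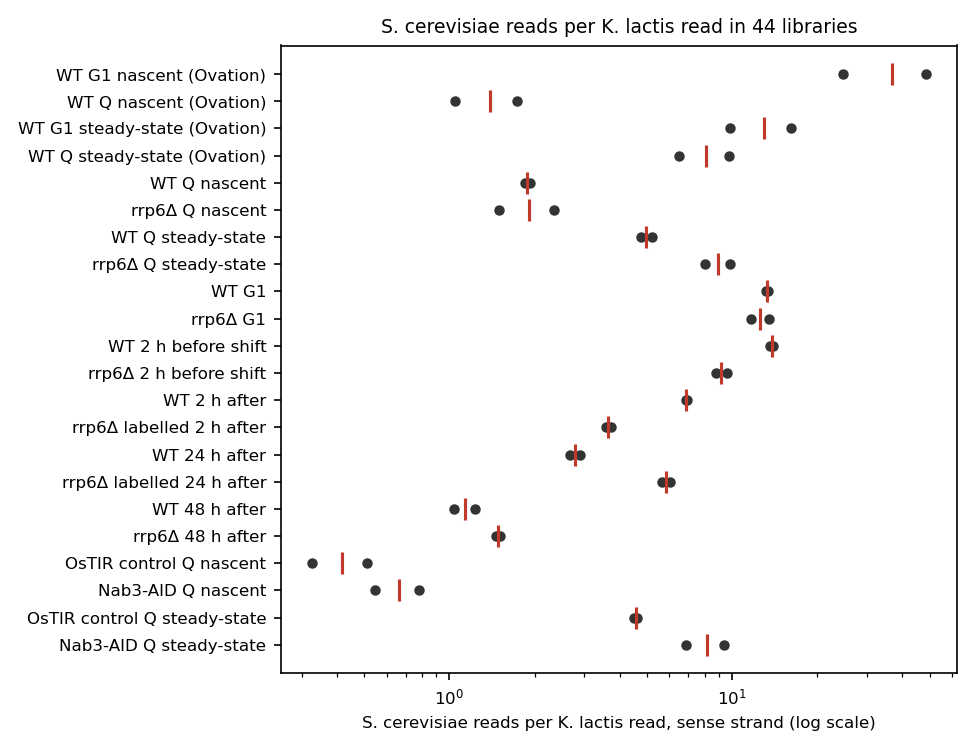
S. cerevisiae reads per K. lactis read in each library of the 22 groups, on a log axis. Dots are libraries and bars are group means.

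To see how the steady-state transcriptome of quiescent wild-type cells differs from that of G1, the day 7 and alpha-factor libraries were compared. SPG1 (YGR236C, chromosome VII, 962530 to 962817), needed for survival in stationary phase, rose by 11.87 ± 0.74 (adjusted p 1.7e-06), and GRE1 (YPL223C, chromosome XVI, 128632 to 129138), a hydrophilin, rose by 11.65 ± 0.44 (adjusted p 5.3e-07). The acetate transporter ADY2 (YCR010C, chromosome III, 132273 to 133124) rose by 11.04 ± 0.49 (adjusted p 5.3e-07). RGI2 (YIL057C, chromosome IX, 247902 to 248396), a respiratory growth gene with 2 counts in G1, had a count ratio of 13210 (95% interval 3656 to 109100). The enolase gene ENO2 (YHR174W, chromosome VIII, 451327 to 452640) changed by -10.17 ± 0.38 and the pyruvate decarboxylase gene PDC1 (YLR044C, chromosome XII, 232390 to 234081) by -9.34 ± 0.40. ASG7 (YJL170C, chromosome X, 101150 to 101779), specific to a cells, changed by -9.84 ± 0.33.

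Of 5970 mRNAs, 2190 were higher and 2266 lower in quiescent steady-state RNA. The heat shock genes HSP26 (YBR072W, chromosome II, 382030 to 382674) and HSP12 (YFL014W, chromosome VI, 107256 to 107585) rose by 7.10 ± 0.35 (adjusted p 7.7e-07) and 7.03 ± 0.26 (adjusted p 5.3e-07). The vitamin B6 gene SNZ1 (YMR096W, chromosome XIII, 458408 to 459301), long used as a stationary-phase marker, rose by 2.43 ± 0.30 (adjusted p 9.1e-05). The mating gene FUS1 (YCL027W, chromosome III, 71803 to 73341) changed by -6.40 ± 0.25, the GTP synthesis gene IMD2 (YHR216W, chromosome VIII, 554396 to 555967) by -4.29 ± 0.38 and the pyrimidine gene URA2 (YJL130C, chromosome X, 165723 to 172367) by -4.66 ± 0.27. NAB3 (YPL190C, chromosome XVI, 185317 to 187725) rose by 1.2 ± 0.21. The helicase gene SEN1 (YLR430W, chromosome XII, 993434 to 1000129), at -0.15 ± 0.19, adjusted p 0.492, and the phosphate transporter gene PHO84 (YML123C, chromosome XIII, 24037 to 25800), at 0.03 ± 0.42, adjusted p 0.952, did not pass, although PHO84 was called without wild-type quiescent steady-state replicate 2 (log2 -0.87, adjusted p 0.0164). NRD1 (YNL251C, chromosome XIV, 172588 to 174315), whose protein pairs with Nab3, was not called at 1.33 ± 0.58, adjusted p 0.0642. It was called without wild-type quiescent steady-state replicate 2 (log2 1.89). The serine synthesis gene SER3 (YER081W, chromosome V, 322686 to 324095) changed by -1.32 ± 0.36. Its call was lost without wild-type quiescent steady-state replicate 2 (log2 -1.20). RRP6 (YOR001W, chromosome XV, 326832 to 329033) itself changed by -0.63 ± 0.16, a call lost without wild-type G1 steady-state replicate 1 (log2 -0.51). K. lactis scaling moved the median of all mRNAs by -0.33 and gave 913 higher (36.2% of calls against 49.2%) and 1610 lower.

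All lists were tested in this comparison. Ribosomal protein genes were lower as a set, with 1 higher and 135 lower of 138 (2 and 135 adjusted over the list alone), a median of -3.98 and camera adjusted p = 7.4e-42, against adjusted p = 0.164 with an estimated correlation. RPS22A (YJL190C, chromosome X, 74910 to 75302) changed by -6.90 ± 0.31 (adjusted p 5.4e-07) and RPL22A (YLR061W, chromosome XII, 263194 to 263948) by -6.56 ± 0.30 (adjusted p 5.8e-07), while RPS22B (YLR367W, chromosome XII, 856442 to 857317) rose by 1.02 ± 0.33 (adjusted p 0.0213). The RPS22B call was lost without 3 of the 4 libraries, as without wild-type quiescent steady-state replicate 2 (log2 0.38). Counts shared by near-identical copies are uncertain. Ribosome biogenesis had 0 higher and 58 lower of 60 (median -2.17, adjusted p = 1.3e-11, and adjusted p = 0.417 with an estimated correlation). Glycolysis had 1 higher and 16 lower of 20 (median -5.16, adjusted p = 2.1e-09, and adjusted p = 0.233 with an estimated correlation), with the glucokinase gene GLK1 (YCL040W, chromosome III, 50838 to 52340) alone higher at 2.50 ± 0.40. The pheromone response had 0 higher and 29 lower of 29 (median -5.02, adjusted p = 2.1e-17, and adjusted p = 0.0526 with an estimated correlation).

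On the other side, gluconeogenesis and glyoxylate cycle genes were higher in 17 of 17 (median 6.30, adjusted p = 3.5e-11, and adjusted p = 0.126 with an estimated correlation), among them the alcohol dehydrogenase gene ADH2 (YMR303C, chromosome XIII, 873291 to 874337) at 9.58 ± 0.37. Stationary-phase genes had 21 higher and 0 lower of 24 (median 4.65, adjusted p = 5.8e-13, and adjusted p = 0.0264 with an estimated correlation). Fatty acid beta-oxidation and peroxisome genes had 18 higher and 0 lower of 20 (median 3.65, adjusted p = 3.0e-11, and adjusted p = 0.114 with an estimated correlation). Autophagy genes had 21 higher and 1 lower of 24 (median 2.94, adjusted p = 1.7e-08, and adjusted p = 0.164 with an estimated correlation). Trehalose and glycogen metabolism had 12 higher and 4 lower of 18 (median 1.10, adjusted p = 0.00272, and adjusted p = 0.233 with an estimated correlation). Meiosis genes had 29 higher and 3 lower of 41 (median 2.01, adjusted p = 0.000445, and adjusted p = 0.305 with an estimated correlation). Core histones had 5 higher and 0 lower of 8 (median 1.47, adjusted p = 0.0444, and adjusted p = 0.305 with an estimated correlation).

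The other lists did not pass. They were the TCA cycle (8 higher, 7 lower of 15, median 0.96, adjusted p = 0.501), respiratory chain and ATP synthase (18 and 9 of 32, median 0.64, adjusted p = 0.2), proteasome (1 and 16 of 33, median -0.45, adjusted p = 0.342), and attenuated genes (1 and 6 of 9, median -2.81, adjusted p = 0.0977). The exosome and Nrd1-Nab3-Sen1 list had 3 and 10 of 21 (median -0.44, adjusted p = 0.335), cytoplasmic mRNA decay 7 and 11 of 24 (median -0.39, adjusted p = 0.714), and the iron regulon 8 and 11 of 26 (median -0.44, adjusted p = 0.558). Heat shock and chaperone genes had 9 and 10 of 26, with a median of -0.31, a mean of 0.50 and a test pointing up (adjusted p = 0.591). Mitosis and G2/M had 10 and 9 of 25, with a median of 0.07, a mean of -0.16 and a test pointing up (adjusted p = 0.959), and its median was -0.24 with K. lactis scaling. S phase and G1/S had 11 and 12 of 30, with a median of 0.08, a mean of -0.15 and a test pointing down (adjusted p = 0.812), and its median was -0.30 with K. lactis scaling. The phosphate regulon had 8 and 5 of 19 (median 0.03, adjusted p = 0.591, and median -0.49 with K. lactis scaling). The mitochondrial ribosome had 17 and 19 of 67 (15 and 18 adjusted over the list alone, median 0.22, adjusted p = 0.728, and median -0.19 with K. lactis scaling).

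The same states were compared in nascent RNA, which asks what is being transcribed. DPA10 (YLR307C-A, chromosome XII, 746848 to 747111) rose by 12.32 ± 1.11 (adjusted p 3.7e-05), the malate synthase gene MLS1 (YNL117W, chromosome XIV, 406358 to 408022) by 10.26 ± 0.94 (adjusted p 4.0e-05) and ADH2 by 9.69 ± 0.37 (adjusted p 1.1e-06). RGI2, with 7 counts in G1, rose by 10.86 ± 0.44. PRM6 (YML047C, chromosome XIII, 180017 to 181075), a potassium transporter gene induced by pheromone, changed by -9.27 ± 0.58, ASG7 by -8.49 ± 0.29 and ENO2 by -8.31 ± 0.35. Of 5970 mRNAs, 1732 were higher and 1977 lower. Scaling to K. lactis moved the median of all mRNAs by -4.43 and left 61 higher and 5561 lower.

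HSP26 and HSP12 rose by 6.84 ± 0.35 and 6.57 ± 0.26 in nascent RNA. FUS1 changed by -7.09 ± 0.25, IMD2 by -2.78 ± 0.34, URA2 by -1.35 ± 0.23 (adjusted p 0.00118) and RRP6 by -0.70 ± 0.16. NRD1 rose by 2.36 ± 0.60 (adjusted p 0.00834), but was -2.37 with K. lactis scaling. Its call was lost without wild-type G1 nascent replicate 2 (log2 2.10) or wild-type quiescent nascent replicate 1 (log2 1.34). SNZ1 rose by 1.71 ± 0.30 and was -2.70 with K. lactis scaling. SER3 (0.26 ± 0.34, adjusted p 0.526), PHO84 (0.21 ± 0.42, adjusted p 0.688) and NAB3 (0.27 ± 0.21, adjusted p 0.284) did not pass, and with K. lactis scaling were -4.40, -4.34 and -4.23. SEN1 did not pass either (-0.13 ± 0.19, adjusted p 0.55). Pheromone response genes, induced by the G1 arrest, had 0 higher and 29 lower of 29. Their median was -5.37 (camera adjusted p = 2.3e-34, and adjusted p = 0.0382 with an estimated correlation). Gluconeogenesis genes had 16 higher and 0 lower of 17 (17 and 0 adjusted over the list alone, median 7.41, adjusted p = 5.7e-22, and adjusted p = 0.0634 with an estimated correlation). Stationary-phase genes had 21 higher and 0 lower of 24 (median 4.03, adjusted p = 1.3e-17, and adjusted p = 0.0144 with an estimated correlation), with a median of -0.40 under K. lactis scaling. Ribosomal protein genes had 1 higher and 132 lower of 138 (1 and 134 adjusted over the list alone, median -1.82, adjusted p = 5.7e-22, and adjusted p = 0.248 with an estimated correlation).

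Whether nascent and steady-state RNA changed by the same amount was tested as an interaction. The nascent minus steady-state value was 4.86 ± 0.56 (adjusted p 9.1e-04) for CYS3 (YAL012W, chromosome I, 130799 to 131983), 4.40 ± 0.40 (adjusted p 5.6e-04) for MET17 (YLR303W, chromosome XII, 732542 to 733876) and 4.32 ± 0.44 (adjusted p 6.1e-04) for SAM1 (YLR180W, chromosome XII, 515262 to 516410), which act in cysteine and methionine synthesis. It was 4.67 ± 0.36 for RPL22A and 3.31 ± 0.33 for URA2, which was -0.82 with K. lactis scaling. It was -4.38 ± 0.86 for DPC7 (YKL065W-A, chromosome XI, 315954 to 316175), -3.21 ± 0.40 for the citrate synthase gene CIT3 (YPR001W, chromosome XVI, 556377 to 557837) and -3.17 ± 0.71 for the thiolase gene POT1 (YIL160C, chromosome IX, 40191 to 41444). SPG1 stood at -3.34 ± 0.85, a call lost without 2 of the 8 libraries, as without wild-type G1 nascent replicate 1 (log2 -2.45).

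Of 5970 mRNAs, 2256 differed between the fractions, 1243 with a higher and 1013 with a lower nascent change. Leaving out wild-type G1 nascent replicate 2 gave 1416. Counts scaled to K. lactis moved the median by -4.11 and left 0 higher and 5453 lower, while 2853 passed an unadjusted 0.05 in the edgeR test with TMM. Ribosomal protein genes had 123 higher and 1 lower of 138 (127 and 1 adjusted over the list alone, median 2.26, camera adjusted p = 7.8e-50, and adjusted p = 0.295 with an estimated correlation), with a median of -1.89 under K. lactis scaling. RPL9B (YNL067W, chromosome XIV, 499681 to 500256) stood at 2.92 ± 0.34 and RPS22A at 3.88 ± 0.36, but at -1.23 and -0.17 with K. lactis scaling. Counts of their near-identical copies are uncertain. Beta-oxidation genes had 1 higher and 14 lower of 20 (1 and 15 adjusted over the list alone, median -1.54, adjusted p = 1.6e-05, and adjusted p = 0.299 with an estimated correlation). Genes reported to be attenuated by Nrd1-Nab3-Sen1 had 5 higher and 0 lower of 9 (7 and 0 adjusted over the list alone, median 1.59, adjusted p = 0.00314, and adjusted p = 0.749 with an estimated correlation), with a median of -2.71 under K. lactis scaling. IMD2 stood at 1.51 ± 0.49 and SER3 at 1.59 ± 0.49, but at -2.66 and -2.71 with K. lactis scaling. The IMD2 call was lost without 5 of the 8 libraries, as without wild-type quiescent nascent replicate 1 (log2 1.06, adjusted p 0.132), and that of SER3 without 6 of them, as without the same library (log2 0.92, adjusted p 0.0851). NAB3 stood at -0.93 ± 0.30, a call lost without 6 of the 8 libraries, as without wild-type quiescent steady-state replicate 1 (log2 -0.56, adjusted p 0.0975). No call was made for NRD1 (1.03 ± 0.81, adjusted p 0.348), SEN1, RRP6, FUS1, HSP12, HSP26, SNZ1 or PHO84, although SNZ1 was called without wild-type quiescent steady-state replicate 1 (log2 -0.97, adjusted p 0.0115) and PHO84 without wild-type quiescent steady-state replicate 2 (log2 1.05, adjusted p 0.0358).

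**Figure D2:**
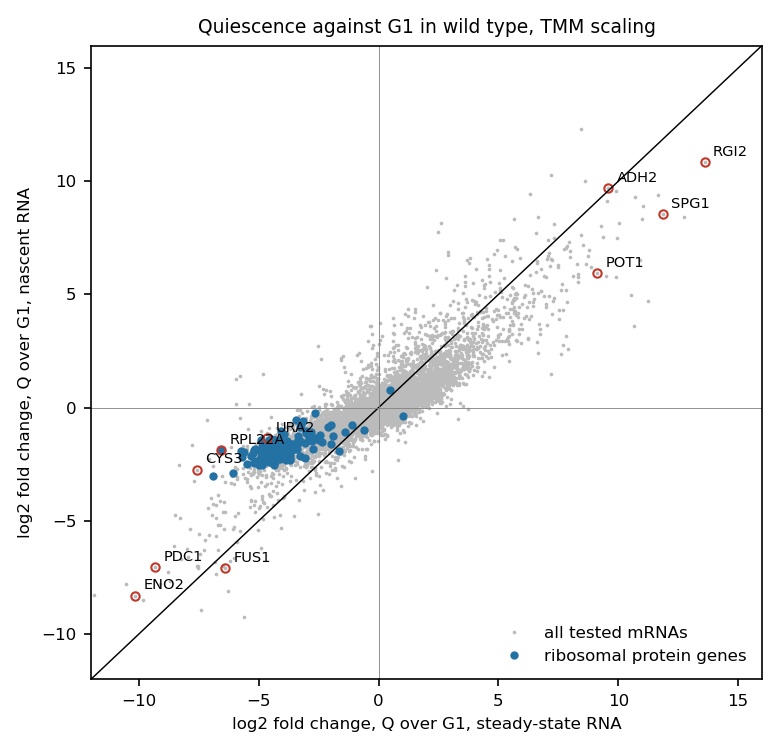
Change from G1 to quiescence in nascent against steady-state RNA, on the log2 scale with TMM scaling, with ribosomal protein genes in blue and 10 named genes circled. Under K. lactis scaling the nascent median of the ribosomal protein genes goes from -1.82 to -6.30 and the median of their interaction from 2.26 to -1.89.

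Noncoding RNAs as a group held a larger share of quiescent than of G1 RNA. Of 3496, 1955 were higher and 386 lower in nascent RNA (median 1.2), and 1436 were higher and 579 lower in steady-state RNA (median 0.87). SRATs, transcripts restrained by Ssu72, had the largest nascent median, 2.26, with 249 higher and 26 lower of 358. XUTs, which Xrn1 degrades, had 880 higher and 107 lower of 1398 (median 1.43), and CUTs, which the exosome degrades, 416 and 68 of 780 (median 1.06). In steady-state RNA, SRATs had 192 higher and 35 lower (median 1.72), XUTs 615 and 160 (median 1.00) and CUTs 264 and 146 (median 0.45). Among nascent noncoding RNAs that overlap no coding gene on their strand, 1601 were higher and 202 lower of 2629 (median 1.47). With K. lactis scaling the nascent median was -3.27, with 42 higher and 2839 lower, and in steady-state RNA it moved by -0.31, with 784 higher and 446 lower. With library sizes of the noncoding table, a scaling that centres these RNAs near 0, the calls were 1082 higher and 974 lower in nascent RNA (median 0.08) and 856 and 998 in steady-state RNA (median -0.05).

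The nascent transcript SUT-SUT243 (chromosome XI, 630541 to 631016) rose by 10.51 ± 0.66 (adjusted p 3.8e-08), XUT-14F-97 (chromosome XIV, 260485 to 260876), antisense to PSY2, rose at least 141-fold, and XUT-3F-78 (chromosome III, 168897 to 169249) changed by -7.99 ± 0.42 (adjusted p 1.5e-08). In steady-state RNA CUT-CUT791 (chromosome XIII, 874389 to 874550), just upstream of the start of ADH2, rose by 10.92 ± 0.63 (adjusted p 1.6e-08). On the strand opposite coding genes, 2619 of 4440 genes were higher and 367 lower in quiescent nascent RNA (median 1.66), and antisense reads of URA2 went from 5 to 397 counts (6.57 ± 0.86). Assembly of nascent reads gave 138 antisense and 74 intergenic noncoding loci in G1, and 835 and 269 in quiescence.

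In quiescent steady-state RNA, deletion of RRP6 was compared with wild-type cells of day 8 to see what the exosome removes from the stored pool. MPC54 (YOR177C, chromosome XV, 665785 to 667179), a meiotic spindle body gene, rose by 2.80 ± 0.28 (adjusted p 0.00245), and HIR2 (YOR038C, chromosome XV, 402761 to 405388), which represses histone genes, by 2.42 ± 0.17 (adjusted p 6.3e-04). TYC1 (YBR296C-A, chromosome II, 800123 to 800242) rose by 4.08 ± 0.52 (adjusted p 0.00483) from 7 counts, a call lost without 2 of the 4 libraries, as without wild-type quiescent steady-state replicate 1 (log2 3.38, adjusted p 0.0522). RRP6 changed by -3.60 ± 0.23 and RPS22B by -2.89 ± 0.19. PHO84 changed by -3.27 ± 0.39, a call lost without either rrp6Δ library, as without replicate 2 (log2 -3.26). PHO89 (YBR296C, chromosome II, 796798 to 798522) changed by -2.65 ± 0.27, a call lost without rrp6Δ quiescent steady-state replicate 2 (log2 -2.43). NRD1 rose by 1.06 ± 0.23, a call lost without any 1 of the 4 libraries, as without rrp6Δ quiescent steady-state replicate 2 (log2 1.03, adjusted p 0.154). FUS1 rose by 1.36 ± 0.33, a call lost without any 1 library, as without rrp6Δ quiescent steady-state replicate 2 (log2 1.16, adjusted p 0.208). SNZ1 changed by -0.73 ± 0.18, was 0.41 with K. lactis scaling, and lost its call without any 1 library, as without rrp6Δ quiescent steady-state replicate 2 (log2 -0.65, adjusted p 0.249). URA2, IMD2, SER3, SEN1, NAB3, HSP12 and HSP26 were not called, and NAB3 and HSP12 were called higher with K. lactis scaling (0.80 and 1.04).

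Of 6170 mRNAs, 294 were higher and 443 lower, and 1842 passed an unadjusted 0.05. Leaving out any 1 library gave far fewer, so most of these calls depend on each library. Only the compared groups in the fit gave 845 higher and 920 lower. Under K. lactis scaling the median moved by 1.14, with 4206 higher and 9 lower, and the Wald test of DESeq2 gave 301 higher (29.2% of calls against 39.9%) and 730 lower. Genes of the phosphate regulon had 0 higher and 10 lower of 19 (0 and 13 adjusted over the list alone, median -0.67, camera adjusted p = 2.5e-10, and adjusted p = 0.287 with an estimated correlation), with a median of 0.48 under K. lactis scaling. Ribosomal protein genes had 20 higher and 1 lower of 138 (46 and 1 adjusted over the list alone, median 0.56, adjusted p = 2.9e-13, and adjusted p = 0.874 with an estimated correlation). RPL18B (YNL301C, chromosome XIV, 63570 to 64562) rose by 1.69 ± 0.22 and lost its call without 3 of the 4 libraries, as without rrp6Δ quiescent steady-state replicate 2 (log2 1.70, adjusted p 0.0682), and counts shared with its near-identical copy are uncertain. Small nucleolar RNAs had 13 higher and 36 lower of 69 (median -0.71), and 17 and 1 in nascent RNA (median 0.58).

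In quiescent nascent RNA of day 8 RRP6 changed by -4.54 ± 0.23 (adjusted p 2.1e-04). PHO84 changed by -2.86 ± 0.38 (adjusted p 0.0179) and the inositol synthesis gene INO1 (YJL153C, chromosome X, 134332 to 135933) by -2.16 ± 0.19 (adjusted p 0.0031). The pyruvate carrier gene MPC2 (YHR162W, chromosome VIII, 423072 to 423461) rose by 2.06 ± 0.20. BSC1 (YDL037C, chromosome IV, 384601 to 385587) rose by 2.28 ± 0.41, a call lost without 3 of the 4 libraries, as without rrp6Δ quiescent nascent replicate 1 (log2 1.5, adjusted p 0.079), and TYC1 by 2.27 ± 0.34, a call lost without 2 of them, as without wild-type quiescent nascent replicate 1 (log2 1.92, adjusted p 0.069). The pyruvate decarboxylase gene PDC6 (YGR087C, chromosome VII, 651290 to 652981) changed by -2.12 ± 0.33, a call lost without 2 libraries, as without rrp6Δ quiescent nascent replicate 2 (log2 -1.72, adjusted p 0.054). NRD1 was not called (-0.03 ± 0.22, adjusted p 0.963), nor were the other genes followed throughout, except HSP26 without wild-type quiescent nascent replicate 1 (log2 -1.34, adjusted p 0.0295). Of 6170 mRNAs, 50 were higher and 25 lower, with 849 at an unadjusted 0.05, and 20 were called without rrp6Δ quiescent nascent replicate 1. With only the compared groups in the fit 5 were called and PHO84 was not. The Wald test of DESeq2 gave 158 higher and 72 lower, and the replicate block 128 and 55. K. lactis scaling, which moved the median by -0.011, gave 33 higher and 17 lower. The phosphate regulon had 0 higher and 4 lower of 19 (0 and 12 adjusted over the list alone, median -0.58, camera adjusted p = 6.6e-17, and adjusted p = 0.137 with an estimated correlation).

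Noncoding RNAs were compared in the same cells. In steady-state RNA of rrp6Δ 1310 were higher and 205 lower of 3931 (median 0.72), and in nascent RNA 642 and 77 (median 0.26). Reads on noncoding RNAs per 100 mRNA reads were 68.9 in rrp6Δ and 96.2 in wild-type cells in steady-state RNA, and 14.9 and 13.9 in nascent RNA. CUTs had 459 higher and 33 lower of 812 (median 1.53) in steady-state RNA and 264 and 7 (median 0.57) in nascent RNA. NUT-NUT1035_CUT-CUT598_CUTHMM-CUT348 (chromosome VII, 357359 to 358401) rose at least 43.8-fold in steady-state RNA. NUT-NUT1320_CUT-CUT789 (chromosome XIII, 761586 to 763113), antisense to the fatty acid activation gene FAA4, changed by -3.63 ± 0.17 (adjusted p 6.0e-09). In nascent RNA CUT-CUT734 (chromosome XII, 363971 to 364300), antisense to the exonuclease gene REX3, rose by 3.43 ± 0.37 (adjusted p 1.0e-04). Fewer passed in nascent RNA without wild-type replicate 1, and 949 were higher and 151 lower with a replicate block. K. lactis scaling moved the steady-state median by 1.15, with 2758 higher and 18 lower (99.4% of calls against 86.5%). It moved the nascent median by -0.021, with 212 and 20. Library sizes of the noncoding table gave 800 higher and 468 lower in steady-state and 335 and 159 in nascent RNA.

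In G1 the deletion was compared in steady-state RNA. The cell wall gene SRL1 (YOR247W, chromosome XV, 797676 to 798308) rose by 3.57 ± 0.11 (adjusted p 1.5e-17). The RNA binding gene MIP6 (YHR015W, chromosome VIII, 134554 to 136533) rose by 3.28 ± 0.12 (adjusted p 2.2e-16) and SWI5 (YDR146C, chromosome IV, 748613 to 750742), a transcription factor of late mitosis, by 2.80 ± 0.17. RRP6 changed by -4.74 ± 0.12, PHO84 by -2.67 ± 0.15 and the vacuolar aminopeptidase gene APE1 (YKL103C, chromosome XI, 246138 to 247682) by -2.22 ± 0.12. NRD1 rose by 2.20 ± 0.09. HSP26 rose by 1.06 ± 0.28, a call lost without wild-type G1 steady-state replicate 1 (log2 0.77, adjusted p 0.0729). HSP12 rose by 0.93 ± 0.17, IMD2 by 0.62 ± 0.16, SEN1 by 0.36 ± 0.08 and NAB3 by 0.33 ± 0.08, and SNZ1 changed by -1.25 ± 0.14. SER3 changed by -0.39 ± 0.13, a call lost without 3 of the 4 libraries, as without wild-type G1 steady-state replicate 1 (log2 -0.36, adjusted p 0.0948). FUS1 (-0.03 ± 0.09, adjusted p 0.804) and URA2 (-0.21 ± 0.11, adjusted p 0.11) did not pass.

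Of 6146 mRNAs, 1567 were higher and 1418 lower in G1, and 552 and 108 by at least 2-fold. With K. lactis scaling, which moved the median by 0.096, 1610 were higher (71.5% of calls against 52.5%) and 643 lower. Mitosis genes had 18 higher and 2 lower of 25 (median 0.47, camera adjusted p = 1.3e-05, and adjusted p = 0.408 with an estimated correlation). The phosphate regulon had 3 higher and 13 lower of 19 (median -0.77, adjusted p = 2.0e-06, and adjusted p = 0.408 with an estimated correlation). The mitochondrial ribosome had 0 higher and 52 lower of 67 (0 and 55 adjusted over the list alone, median -0.37, adjusted p = 1.3e-06, and adjusted p = 0.409 with an estimated correlation). Of 3903 noncoding RNAs, 2697 were higher and 137 lower (median 1.39), and CUTs had 704 higher and 23 lower of 825 (median 2.28). CUT-CUT350 (chromosome XIV, 716433 to 716706), which lies in no gene, rose by 6.46 ± 0.23 (adjusted p 2.3e-36). Antisense reads of HSP26 went from 2 to 168 counts, and those of PHO84 rose by 2.08 ± 0.17. K. lactis scaling moved the noncoding median by 0.105, and library sizes of the noncoding table gave 1114 higher and 1168 lower.

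The rrp6Δ strain was next followed around the diauxic shift. At 2 h before it the maltase gene MAL12 (YGR292W, chromosome VII, 1076599 to 1078353) rose by 5.46 ± 0.28 (adjusted p 3.4e-13), the pyruvate decarboxylase gene PDC5 (YLR134W, chromosome XII, 410723 to 412414) by 4.54 ± 0.35 (adjusted p 6.7e-07) and the heat shock gene HSP30 (YCR021C, chromosome III, 156109 to 157107) by 3.70 ± 0.43 (adjusted p 8.9e-06). RRP6 changed by -5.65 ± 0.14 and APE1 by -2.62 ± 0.10. NRD1 rose by 3.14 ± 0.09, HSP26 by 2.05 ± 0.21, HSP12 by 1.98 ± 0.17, SNZ1 by 1.42 ± 0.15 and SER3 by 0.95 ± 0.13. PHO84 changed by -0.44 ± 0.14, a call lost without 2 of the 4 libraries, as without wild-type 2 h before shift steady-state replicate 1 (log2 -0.36, adjusted p 0.0739). Stationary-phase genes had 21 higher and 1 lower of 24 (median 1.53, camera adjusted p = 2.9e-09, and adjusted p = 0.137 with an estimated correlation), with SPG4 (YMR107W, chromosome XIII, 483014 to 483361) at 4.03 ± 0.49 and GRE1 at 3.26 ± 0.30. Core histones had 0 higher and 8 lower of 8 (median -0.91, adjusted p = 1.1e-05, and adjusted p = 0.182 with an estimated correlation). The mitochondrial ribosome had 1 higher and 65 lower of 67 (median -0.74, adjusted p = 4.5e-20, and adjusted p = 0.127 with an estimated correlation). Of 6146 mRNAs, 1917 were higher and 1948 lower. Scaled to K. lactis reads, the median moved by -0.41, with 973 higher (22.3% of calls against 49.6%) and 3397 lower.

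In the libraries labelled 2 h after the shift, whose mRNA profile lay nearer to wild-type 24 h (r 0.967 and 0.97 across genes, which are not independent replicates) than to wild-type 2 h (0.923 and 0.93), NCA3 (YJL116C, chromosome X, 193860 to 194873), tied to mitochondrial ATP synthase, rose by 8.25 ± 0.26 (adjusted p 1.3e-13), the thiamine gene THI4 (YGR144W, chromosome VII, 780399 to 781379) by 5.27 ± 0.23 (adjusted p 1.4e-15), PDC6 by 5.13 ± 0.19 (adjusted p 2.5e-13) and the spore wall gene SPS100 (YHR139C, chromosome VIII, 378219 to 379199) by 4.64 ± 0.19. The arginine gene ARG1 (YOL058W, chromosome XV, 219211 to 220473) changed by -4.25 ± 0.26, and RRP6 by -3.39 ± 0.15. NRD1 rose by 2.35 ± 0.09, IMD2 by 1.63 ± 0.21, URA2 by 1.12 ± 0.11, SNZ1 by 1.00 ± 0.14 and HSP26 by 0.94 ± 0.18, while HSP12 changed by -1.32 ± 0.16. Ribosomal protein genes had 135 higher and 0 lower of 138 (median 1.68, camera adjusted p = 1.4e-79, and adjusted p = 0.0205 with an estimated correlation), with RPS9A (YPL081W, chromosome XVI, 404950 to 406044) at 4.00 ± 0.21, whose near-identical copy leaves its counts uncertain. The mitochondrial ribosome had 0 higher and 67 lower of 67 (median -1.17, adjusted p = 3.6e-25, and adjusted p = 0.0205 with an estimated correlation). With the rrp6Δ labels of 2 h and 24 h exchanged PDC6 was -0.95, SPS100 -1.94, HSP26 -1.15 and SNZ1 -1.37. The mitochondrial ribosome median then lay 0.05 above the median of all mRNAs. Of 6146 mRNAs, 1973 were higher and 1906 lower. Scaling to K. lactis moved the median by -0.79 and gave 640 higher (12.8% of calls against 50.9%) and 4341 lower.

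In the libraries labelled 24 h after the shift, whose mRNA profile lay nearer to wild-type 2 h (r 0.937) than to wild-type 24 h (0.903 and 0.902), SPS100 changed by -8.18 ± 0.23 (adjusted p 1.3e-16), PDC6 by -7.30 ± 0.21 (adjusted p 6.0e-15) and GRE1 by -7.27 ± 0.21 (adjusted p 3.6e-19). The mannitol dehydrogenase gene DSF1 (YEL070W, chromosome V, 19589 to 21097) rose by 4.48 ± 0.25. RRP6 changed by -5.11 ± 0.15 and NRD1 rose by 3.09 ± 0.09. IMD2 rose by 2.72 ± 0.21, while HSP26 changed by -2.64 ± 0.19, SNZ1 by -2.34 ± 0.14 and PHO84 by -2.04 ± 0.14. URA2 changed by -0.83 ± 0.11 and was 0.58 with K. lactis scaling. Stationary-phase genes had 0 higher and 21 lower of 24 (median -1.80, camera adjusted p = 8.2e-17, and adjusted p = 0.0645 with an estimated correlation). The mitochondrial ribosome had 65 higher and 0 lower of 67 (median 1.23, adjusted p = 2.1e-19, and adjusted p = 0.0645 with an estimated correlation). Of 6146 mRNAs, 1974 were higher and 2115 lower, against 2113 and 1587 without rrp6Δ replicate 1, and 854 and 1299 with the labels exchanged, where SNZ1 was 0.03. Under K. lactis scaling the median moved by 1.41, with 5575 higher (96.7% of calls against 48.3%) and 191 lower.

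At 48 h after the shift TYC1 rose by 4.68 ± 0.39 (adjusted p 1.9e-09), SRL1 by 2.34 ± 0.18 (adjusted p 4.4e-10) and the peptidyl-tRNA hydrolase gene PTH4 (YOL114C, chromosome XV, 103317 to 103925) by 2.27 ± 0.32 (adjusted p 3.3e-06). The zinc transporter genes ZRT1 (YGL255W, chromosome VII, 20978 to 22108) and ZRT2 (YLR130C, chromosome XII, 402794 to 404062) changed by -3.01 ± 0.25 and -2.56 ± 0.11, RRP6 by -4.61 ± 0.16 and RPS22B by -2.34 ± 0.11, with the uncertainty of a paralog. NRD1 rose by 1.34 ± 0.09. PHO84 changed by -1.08 ± 0.14, SNZ1 by -1.05 ± 0.13 and HSP26 by -1.10 ± 0.18. Stationary-phase genes had 0 higher and 19 lower of 24 (median -0.69, camera adjusted p = 4.8e-07, and adjusted p = 0.422 with an estimated correlation), and the phosphate regulon 1 higher and 13 lower of 19 (median -0.58, adjusted p = 5.1e-05, and adjusted p = 0.43 with an estimated correlation), with medians of 0.11 and 0.22 under K. lactis scaling. Of 6146 mRNAs, 1189 were higher and 1683 lower, and 1819 were called without wild-type replicate 1. Scaled to K. lactis reads, the median moved by 0.80, with 4641 higher (98.4% of calls against 41.4%) and 76 lower.

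Whether the effect of the deletion differed between the libraries labelled 24 h and those of 2 h before the shift was tested as an interaction, and 1777 of 6146 mRNAs had a higher and 2031 a lower effect at 24 h, against 2156 and 1418 without rrp6Δ 24 h replicate 1. SPS100 differed by -11.05 ± 0.55 (adjusted p 1.5e-12), GRE1 by -10.53 ± 0.33 (adjusted p 8.3e-18) and PDC6 by -9.54 ± 0.44 (adjusted p 8.3e-12). The hexose transporter gene HXT1 (YHR094C, chromosome VIII, 290913 to 292625) differed by 4.53 ± 0.48 and ARG1 by 4.13 ± 0.35. HSP26 differed by -4.69 ± 0.28, SNZ1 by -3.76 ± 0.21 and IMD2 by 2.39 ± 0.27. PHO84 differed by -1.61 ± 0.19 and was 0.22 with K. lactis scaling. NRD1 (-0.05 ± 0.13, adjusted p 0.742) and RRP6 (0.54 ± 0.29, adjusted p 0.111) did not pass, and NRD1 was 1.77 with K. lactis scaling. Stationary-phase genes had 1 higher and 23 lower of 24 (median -3.89, camera adjusted p = 5.0e-25, and adjusted p = 0.0164 with an estimated correlation). The mitochondrial ribosome had 66 higher and 0 lower of 67 (66 and 1 adjusted over the list alone, median 1.96, adjusted p = 3.4e-40, and adjusted p = 0.0164 with an estimated correlation). Counts scaled to K. lactis moved the median by 1.81 and gave 5165 higher (95.4% of calls against 46.7%) and 250 lower.

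Wild-type cells give the normal course of the shift. At 2 h after it compared with 2 h before, MLS1 rose by 12.91 ± 0.28 (adjusted p 1.2e-21), the gluconeogenesis genes FBP1 (YLR377C, chromosome XII, 873746 to 874792) and PCK1 (YKR097W, chromosome XI, 631152 to 632801) by 12.41 ± 0.22 (adjusted p 1.0e-23) and 10.99 ± 0.19 (adjusted p 5.2e-24). The hexose transporter gene HXT3 (YDR345C, chromosome IV, 1162957 to 1164660) changed by -6.76 ± 0.17 and HXT1 by -5.96 ± 0.21. HSP26 rose by 6.94 ± 0.24 and SNZ1 by 1.86 ± 0.15, while IMD2 changed by -3.45 ± 0.19, URA2 by -1.93 ± 0.11 and RRP6 by -1.09 ± 0.09. Ribosomal protein genes had 0 higher and 137 lower of 138 (median -3.82, camera adjusted p = 2.4e-100, and adjusted p = 0.0191 with an estimated correlation), and counts of their near-identical copies are uncertain. Gluconeogenesis genes had 17 higher and 0 lower of 17 (median 8.41, adjusted p = 1.1e-23, and adjusted p = 0.0191 with an estimated correlation). Of 6146 mRNAs, 2527 were higher and 2268 lower. With K. lactis scaling the median moved by -0.94, with 1030 higher (20.6% of calls against 52.7%) and 3965 lower.

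At 48 h compared with 2 h before the shift, ADY2 rose by 14.27 ± 0.61 (adjusted p 9.6e-11) from 4 counts, SPG1 by 13.95 ± 0.31 (adjusted p 1.2e-19), GRE1 by 13.61 ± 0.29 (adjusted p 4.4e-23) and SPG4 by 13.28 ± 0.30. RGI2, with 2 counts before the shift, had a count ratio of 21460 (95% interval 5939 to 177200). The acid phosphatase gene PHO3 (YBR092C, chromosome II, 427698 to 429101) changed by -7.86 ± 0.37. HSP26 rose by 6.79 ± 0.24 and SNZ1 by 5.04 ± 0.16. HSP12 rose by 3.65 ± 0.18, NRD1 by 1.32 ± 0.09 and NAB3 by 1.44 ± 0.08, but with K. lactis scaling they were -0.10, -2.42 and -2.30. Stationary-phase genes had 23 higher and 1 lower of 24 (median 5.83, camera adjusted p = 7.0e-16, and adjusted p = 0.134 with an estimated correlation). Ribosomal protein genes had 1 higher and 136 lower of 138 (median -3.10, adjusted p = 6.4e-40, and adjusted p = 0.143 with an estimated correlation), with the same limit for near-identical copies. Of 6146 mRNAs, 2545 were higher and 2670 lower. Scaled to K. lactis reads, the median moved by -3.75, with 273 higher (4.68% of calls against 48.8%) and 5559 lower.

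**Figure D3:**
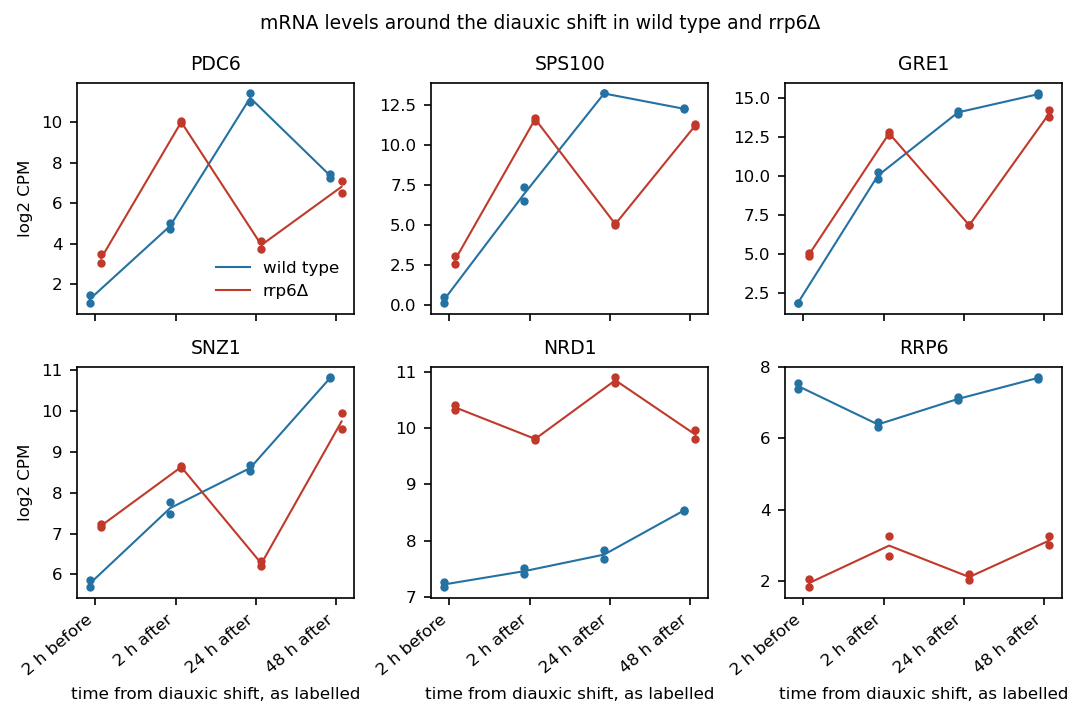
Log2 CPM of PDC6, SPS100, GRE1, SNZ1, NRD1 and RRP6 in wild-type and rrp6Δ cells at the 4 labelled times. Dots are libraries and lines join group means.

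Noncoding RNAs of rrp6Δ and wild-type cells were compared at each labelled time. Of 3903, 2844 were higher and 198 lower at 2 h before the shift (median 1.58), 2654 and 236 in the libraries labelled 2 h (median 1.41), 2291 and 465 in those labelled 24 h (median 1.17), and 1603 and 319 at 48 h (median 0.80). CUTs had medians of 2.42, 2.13, 2.04 and 1.48 in that order. CUT-CUT350 rose by 7.43 ± 0.28 (adjusted p 4.6e-35) in the libraries labelled 2 h and by 6.07 ± 0.36 (adjusted p 7.4e-24) at 48 h. NUT-NUT0121 (chromosome IV, 544786 to 545818) rose at least 87.7-fold at 2 h before the shift. NUT-NUT1058 (chromosome VII, 651452 to 653338), which overlaps PDC6 on its strand, changed by -7.13 ± 0.17 (adjusted p 1.7e-46) in the libraries labelled 24 h, and NUT-NUT1320_CUT-CUT789 by -2.76 ± 0.11 at 48 h. At 2 h before the shift small nucleolar RNAs had 54 higher and 2 lower of 69 (median 2.13), against 14 and 20 at 48 h (median -0.34), and transposable elements 123 higher and 0 lower of 231 (median 1.12), and counts of their near-identical copies are uncertain. Spike scaling to K. lactis moved the noncoding medians by -0.40, -0.78, 1.39 and 0.77 in the order of the times, with 1659 higher (70.4% of calls against 91.8%) and 697 lower in the libraries labelled 2 h, 3561 and 63 at 24 h, and 2868 and 33 at 48 h. Library sizes of the noncoding table gave 1244 higher and 1071 lower, 1130 and 1099, 1305 and 1173, and 803 and 955 in the same order.

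Nab3 depletion was compared with the auxin control in quiescence to ask what Nrd1-Nab3-Sen1 termination restrains there. In steady-state RNA the cell wall gene ZPS1 (YOL154W, chromosome XV, 34658 to 35407) rose by 4.96 ± 0.36 (adjusted p 4.2e-07), the bud neck gene TOS2 (YGR221C, chromosome VII, 937124 to 938992) by 4.96 ± 0.60 (adjusted p 8.5e-04) and the kinetochore gene NKP1 (YDR383C, chromosome IV, 1239960 to 1240676) by 4.57 ± 0.35 (adjusted p 1.8e-08). The ubiquitin ligase gene ASR1 (YPR093C, chromosome XVI, 719558 to 720424) changed by -4.86 ± 0.16, PDC1 by -4.38 ± 0.20, SPG1 by -4.17 ± 0.18 and SPT10 (YJL127C, chromosome X, 182298 to 184220), a regulator of histone genes, by -4.06 ± 0.29. NRD1 rose by 3.42 ± 0.16 and SER3 by 2.32 ± 0.21. PHO84 changed by -3.06 ± 0.13 and HSP26 by -2.16 ± 0.15. NAB3 changed by -0.52 ± 0.11 and SNZ1 by -1.41 ± 0.10, but with K. lactis scaling they were 1.15 and 0.28. RRP6 changed by -0.53 ± 0.16, was 1.18 with K. lactis scaling, and lost its call without 2 of the 4 libraries, as without Nab3-AID quiescent steady-state replicate 2 (log2 -0.39, adjusted p 0.0621). IMD2 was not called (2.24 ± 0.95, adjusted p 0.0892) but was called without Nab3-AID quiescent steady-state replicate 1 (log2 2.71, adjusted p 0.0271). Beta-oxidation and peroxisome genes had 1 higher and 18 lower of 20 (median -1.84, camera adjusted p = 3.3e-17, and adjusted p = 0.0276 with an estimated correlation). Attenuated genes had 7 higher and 0 lower of 9 (median 1.45, adjusted p = 9.1e-06, and adjusted p = 0.0894 with an estimated correlation). Of 6135 mRNAs, 1986 were higher and 1882 lower, and 1188 and 887 by at least 2-fold. K. lactis scaling moved the median by 1.69 and gave 4839 higher (98.6% of calls against 51.3%) and 70 lower.

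In nascent RNA ZPS1 rose by 4.71 ± 0.28 (adjusted p 7.0e-08), TOS2 by 4.11 ± 0.44 (adjusted p 4.1e-04), PTH4 by 4.07 ± 0.21 (adjusted p 8.1e-11) and NKP1 by 3.98 ± 0.18. ASR1 changed by -4.43 ± 0.14, and SPT10 by -4.33 ± 0.17. NRD1 rose by 2.34 ± 0.14, SER3 by 2.27 ± 0.17 and URA2 by 1.85 ± 0.09. IMD2 rose by 3.22 ± 0.72, a call lost without either OsTIR-AID library, as without replicate 1 (log2 3.29, adjusted p 0.0846). PHO84 changed by -2.91 ± 0.13 and HSP26 by -1.97 ± 0.15. RRP6 changed by -0.73 ± 0.13, and was 0.34 with K. lactis scaling. SEN1 did not pass (0.05 ± 0.09, adjusted p 0.597). Attenuated genes had 7 higher and 0 lower of 9 (median 1.85, camera adjusted p = 3.0e-05, and adjusted p = 0.0993 with an estimated correlation). Beta-oxidation genes had 2 higher and 17 lower of 20 (median -1.43, adjusted p = 5.4e-11, and adjusted p = 0.0993 with an estimated correlation), with POT1 at -2.39 ± 0.10. Of 6135 mRNAs, 2211 were higher and 2079 lower. Under K. lactis scaling the median moved by 1.09, with 3513 higher (96.9% of calls against 51.5%) and 112 lower.

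Of 3881 noncoding RNAs, 2869 were higher and 348 lower without Nab3 in nascent RNA (median 1.74), and 2387 and 377 in steady-state RNA (median 1.70). CUTs had 710 higher and 37 lower of 812 in nascent RNA (median 2.60) and 637 and 57 in steady-state RNA (median 2.69). Small nucleolar RNAs had 17 higher and 18 lower of 68 in nascent RNA (median -0.19) and 3 and 59 in steady-state RNA (median -2.16). Noncoding reads per 100 mRNA reads were 31.4 without Nab3 and 17.8 in the control in nascent RNA, but 79.4 and 134 in steady-state RNA. These include SCR1 and RPR1, which fell there (-2.12 and -2.61). CUTHMM-CUT1285 (chromosome IV, 681858 to 682118), which lies in no gene, rose at least 90.1-fold in nascent RNA, and NUT-NUT1020 (chromosome VII, 206362 to 208578), antisense to the kinase gene RCK1, at least 63.5-fold in steady-state RNA. XUT-1R-101 (chromosome I, 206239 to 206695), antisense to the flocculin gene FLO1, changed by -4.11 ± 0.19 (adjusted p 6.2e-17) in nascent RNA. On the strand opposite coding genes, 4482 of 5866 genes were higher and 423 lower in nascent RNA (median 1.97). Antisense reads of URA2 went from 99 to 1770 counts (3.20 ± 0.19) and those of RRP6 from 23 to 1266 (4.83 ± 0.27). Antisense reads of PHO84 changed by -0.86 ± 0.29. Scaling to K. lactis moved the noncoding median by 1.09 in nascent and 1.69 in steady-state RNA, where it gave 3440 higher (98.7% of calls against 86.4%) and 44 lower. Library sizes of the noncoding table gave 1581 higher and 1338 lower in nascent RNA (median 0.22) and 1138 and 1032 in steady-state RNA (median 0.32).

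**Figure D4:**
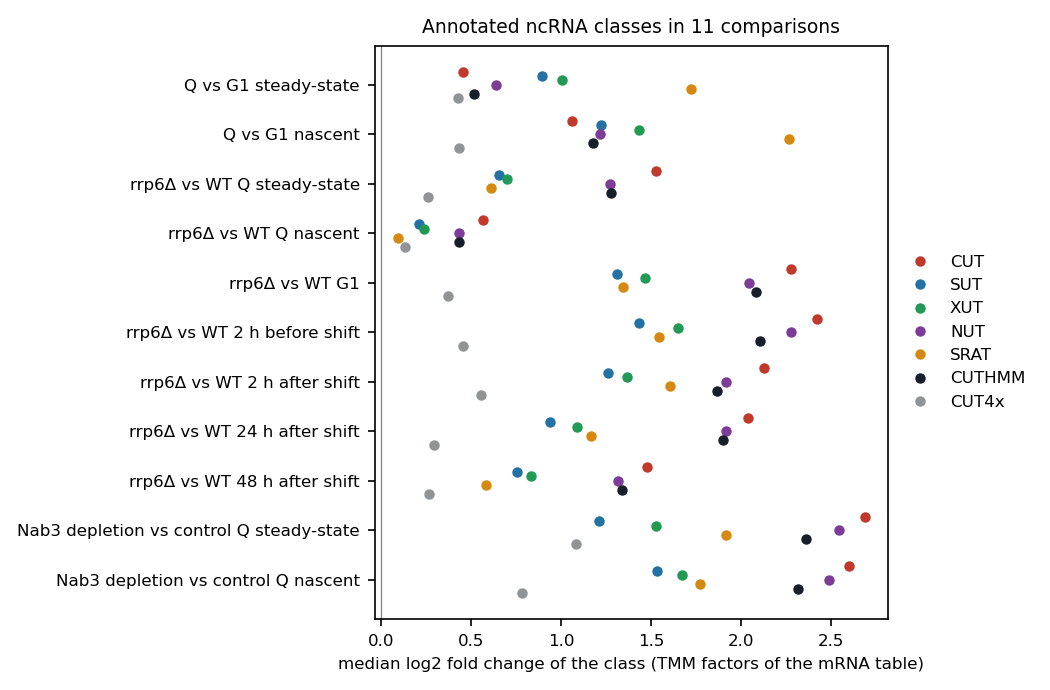
Median log2 change of each class of noncoding RNA in the 11 comparisons. With K. lactis scaling the median of all noncoding RNAs in quiescent against G1 nascent RNA goes from 1.2 to -3.27, and library sizes of the noncoding table centre the medians near 0.

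The noncoding RNAs raised by each loss in quiescent nascent RNA were compared. Of 3754 tested in both, 629 were higher in rrp6Δ and 2747 after Nab3 depletion, and 586 were in both, where 460.3 would be shared if the calls were unrelated (odds ratio 6.08, 95% interval 4.41 to 8.57, Fisher two-sided p = 7.2e-43). Of those higher in rrp6Δ, 93.2% were higher after Nab3 depletion, against 73.2% of all. Changes correlated across noncoding RNAs, which are not independent replicates (Pearson 0.459, Spearman 0.480). Among calls of at least 2-fold, 379 of 404 in rrp6Δ were shared, and among RNAs with no coding gene on their strand 490 of 518. Each strain had its own control.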

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

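The place of the rrp6Δ libraries along the wild-type course and the comparison of the nascent with the steady-state read ratio were tests chosen after these results had been seen, while the other tests below were written down before they were run.

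The interaction of the deletion with time was picked out because an effect that changes between groups is easily missed: 3808 mRNAs had a different effect of the RRP6 deletion in the libraries labelled 24 h than in those of 2 h before the shift. On the path of mRNA levels that wild-type cells take from 2 h before the shift (0) to 48 h after it (100), the rrp6Δ libraries lay at 9.79 and 9.08, then 64.8 and 64.2 at the label 2 h, 32.8 and 31.9 at the label 24 h, and 90.3 and 91.8 at 48 h. The 24 h label minus the 2 h label was -32.12 percent of the path, where replicates differed by 0.9 at most, but this test presumes the labels: with labels exchanged the positions run in order, so it cannot tell whether rrp6Δ cells are only slower. In noncoding RNAs that overlap no coding gene on their strand, 4 of 4 of these libraries lay nearer to the other time, as an exchange of labels would give, but with exchanged labels the calls over both times were 0.7536 of those with the labels as given, just above the bound of 0.75 set for an exchange, so this test cannot tell. SPS100, PDC6 and GRE1, with the largest interaction, may thus owe part of their change to the time labels. What stays open is whether rrp6Δ cells or the labels are out of order, with or without a slower course.

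The nascent against steady-state interaction was picked out by the same rule, with 2256 mRNAs, and 123 of 138 ribosomal protein genes were higher (camera adjusted p = 7.8e-50, and adjusted p = 0.295 with an estimated correlation). K. lactis scaling moved the median of all mRNAs by -4.11, which by itself puts the calls on the lower side. S. cerevisiae reads per K. lactis read fell 25.7-fold from G1 to quiescence in nascent RNA (geometric means), 16.22 times the fall in steady-state RNA. More K. lactis material in quiescent samples would give equal falls if the same addition served both fractions, which the labels do not say, so this test cannot tell. A lower rate of transcription or weaker uptake of 4-thiouracil by quiescent cells could also give the difference, and neither was tested.

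The antisense strand of coding genes was picked out because the series text describes no test of it: 4905 genes changed on that strand after Nab3 depletion in nascent RNA, and 3135 in rrp6Δ G1 cells. Antisense reads of RRP6 rose by 4.83 ± 0.27 and those of URA2 by 3.20 ± 0.19 in nascent RNA without Nab3. Per 100 sense reads of mRNAs there were 28.2 ± 0.746 antisense reads in Nab3-AID and 8.39 ± 0.342 in the control (SD). The antisense reads per sense read of K. lactis in the same libraries were 0.9231 of those in the control, which argues against a loss of strand information, and 63.89% of the gain lay in the 10% of genes with the largest gain, where the longest 10% hold 28.6% of gene length, which argues against an even background. Read-through from noncoding transcripts that Nab3 normally ends could explain the gain and was not tested.

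The 20S RNA replicon was picked out because the sources name it only as part of the joined genome. Wild-type quiescent steady-state libraries of day 8 held 10.4 ± 0.115 reads of 20S RNA per S. cerevisiae read, and those of day 7, made with the other kit, held 0.291 ± 0.124. Day 7 libraries with auxin, made with the kit of day 8, held 8.39 ± 0.943 in OsTIR-AID and 7.13 ± 2 in Nab3-AID.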

How the results depend on the processing

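Groups of 2 limit every result here, and leaving out 1 library leaves 1 sample in an arm, then assumed to vary like the other groups. Directions were compared only where a gene was called under at least 1 setting. Of the counts and read ratios under other settings 387 stayed and 41 moved. The 41 were 9 ratios, beyond their SD, and counts, beyond 1.5 times. With n = 2, leaving out 1 library cannot move a ratio past its SD. Of values of named genes 5841 stayed, 204 weakened, 49 strengthened and 57 reversed, and of lists 434 stayed, 1 weakened and 1 reversed. The cause of these differences was not tested. DESeq2 size factors, no filter on low counts, the first run only (no test in sets without second runs) and batch as a term moved no count.

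K. lactis scaling, which takes RNA per spike rather than the share of mRNA, moved 9 counts of calls: to 2523 and 5622 for quiescence against G1 in steady-state and nascent RNA, 5453 for their interaction, 4215 for rrp6Δ in quiescent steady-state RNA and 4717 at 48 h, and for noncoding RNAs to 1230 for quiescence against G1 and 2776 for rrp6Δ in steady-state RNA, 232 for rrp6Δ in nascent RNA and 2901 at 48 h. Counts that it did not move could still change their split of higher and lower calls, as given with each comparison. It reversed genes as well. In nascent quiescence against G1, SER3 was -4.40, PHO84 -4.34, SNZ1 -2.70, NRD1 -2.37, NAB3 -4.23 and RPL15B -3.62. In the interaction of the fractions SER3 was -2.71, IMD2 -2.66, URA2 -0.82, SEN1 -4.09, PHO84 -3.84, NRD1 -3.51, RPS22A -0.17, PEX21 -2.52 and RPL9B -1.23. In rrp6Δ quiescent steady-state RNA HSP12 was 1.04, SNZ1 0.41 and NAB3 0.80. At 2 h before the shift SEN1 was -0.065 and MRP8 -0.011 in rrp6Δ, at the label 2 h FUS1 was -0.66, SEN1 -0.36 and NAB3 -0.41, and at the label 24 h URA2 was 0.58 and SEN1 1.06. At 48 h HSP12 was 0.44, URA2 0.50, SEN1 0.73 and NAB3 0.48. In wild-type cells SER3 was -0.74, NRD1 -0.71 and NAB3 -0.74 at 2 h, and HSP12 -0.10, SEN1 -2.97, NRD1 -2.42, RRP6 -3.53, NAB3 -2.30 and RPS22B -2.89 at 48 h. In the interaction of rrp6Δ with time HSP12 was 0.15, URA2 1.37, SEN1 1.12, PHO84 0.22, NRD1 1.77 and NAB3 1.55. After Nab3 depletion HSP12 was 0.66, SNZ1 0.28, RRP6 1.18 and NAB3 1.15 in steady-state RNA, and SNZ1 0.61, RRP6 0.34 and NAB3 0.81 in nascent RNA.

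With the labels of rrp6Δ 2 h and 24 h exchanged, a setting added after the data had been seen, calls at 24 h went from 4089 to 2153. PDC6 was -0.95, SPS100 -1.94, HSP26 -1.15 and SNZ1 -1.37 at 2 h, and the mitochondrial ribosome list was 0.0495 above the median of all mRNAs. SNZ1 was 0.026 at 24 h. Fits without these 4 libraries moved no count.

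Only the compared groups in the fit gave 1765 calls for rrp6Δ in quiescent steady-state RNA and 5 in nascent RNA. The Wald test of DESeq2 gave 230 in nascent RNA. The labels do not say that a replicate number marks a shared batch or day across genotypes. Replicate differences correlated across genes at 0.643 between rrp6Δ and wild-type nascent RNA of day 8, at -0.055 to 0.116 in the other 3 pairs of day 8 groups, -0.061 to 0.157 in 25 pairs of RNA-seq groups and -0.049 to 0.056 in 4 pairs of auxin groups. The replicate block gave 183 calls for rrp6Δ in quiescent nascent RNA and 1100 for its noncoding RNAs, and moved no other count.

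The noncoding table before merging gave 793 calls for rrp6Δ in quiescent steady-state RNA, 312 in nascent RNA and 1157 at 48 h. Shared calls of at least 2-fold between rrp6Δ and Nab3 depletion were 379. With reads of both strands, S. cerevisiae reads per K. lactis read were 4.76 in OsTIR-AID quiescent steady-state RNA, 9.84, 3.92, 6.25 and 1.61 in rrp6Δ at the labels 2 h before and 2 h, 24 h and 48 h after the shift, 14.4 and 7.10 in wild-type cells at 2 h before and 2 h after, 13.9 in wild-type G1, and 1.98 in wild-type quiescent nascent RNA.

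Leaving out 1 library moved 13 counts. It gave 1416 to 2672 calls for the interaction of the fractions, 23 to 193 for rrp6Δ in quiescent steady-state RNA, 20 to 95 in nascent RNA, 1819 to 2595 at 48 h, and 441 to 740 for noncoding RNAs of rrp6Δ in quiescent nascent RNA. PHO84 in steady-state quiescence against G1 was -0.87 without wild-type quiescent replicate 2.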

Other observations

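In steady-state RNA of rrp6Δ NRD1 rose at each time and in G1. In quiescence its steady-state rise, a call lost without any 1 library, was not seen in nascent RNA (-0.03 ± 0.22). After Nab3 depletion NRD1 rose in both fractions. URA2, SER3 and IMD2 (a call lost without either control library) rose after Nab3 depletion in nascent RNA. PHO84 mRNA was lower in rrp6Δ and after Nab3 depletion in quiescence, but its antisense reads rose by 1.3 ± 0.22 in rrp6Δ nascent RNA and changed by -0.86 ± 0.29 without Nab3.

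Among genes with an antisense rise of at least 2-fold after Nab3 depletion in nascent RNA, 37.2% had lower sense RNA, against 32.9% of the others (Fisher two-sided p = 0.00189), while in steady-state RNA 31.5% and 32.9% had (Fisher two-sided p = 0.315). Between quiescence and G1 in nascent RNA the shares were 34.2% and 22.9% (Fisher two-sided p = 2.0e-14), and in rrp6Δ steady-state RNA they went the other way, with 21.7% and 25.5% in G1, 28.9% and 36.2% at 2 h before the shift, 29.1% and 34.1% at the label 2 h, 19.3% and 32.1% at 48 h and 4.32% and 8.88% in quiescence, but 36.6% and 34.9% at the label 24 h. Of 169 transposable elements 79 were higher and 12 lower in nascent RNA after Nab3 depletion, and 50 and 29 in steady-state RNA.

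The 20S RNA is a replicon without a coat. Wild-type cells held 0.021, 0.048, 0.697 and 2.81 reads of it per S. cerevisiae read at the 4 times around the shift and 0.048 in G1, against 10.4 ± 0.115 in quiescence at day 8. In libraries of the other kit they held 0.291 ± 0.124 in quiescence at day 7 and 0.00203 in G1. Per K. lactis read the wild-type values went only from 0.275 and 0.314 at 2 h before the shift to 2.71 and 3.71 at 48 h, with 0.62 and 0.668 in G1. Per S. cerevisiae read the labelled times of rrp6Δ gave 0.091, 0.532, 0.129 and 2.28. These were out of order at the same labels as the mRNAs, so 20S RNA may follow the same cause. Quiescent rrp6Δ cells of day 8 held 6.63 ± 0.45 (exact permutation p = 0.333), but per K. lactis read they held 68.0 and 50.4 against 49.8 and 53.5 in wild-type cells.

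HXT6, a hexose transporter gene, had a log2 CPM of 1.09 and 0.43 in Nab3-AID replicate 2 and 0.65 and -0.96 in OsTIR-AID replicate 1, against 6.15 to 7.39 in the other replicates. HIS3 was lower in replicate 2 of rrp6Δ in G1 (6.22 against 8.25) and in quiescent steady-state RNA (4.05 against 7.49), but not at the times around the shift. In the Ovation libraries of wild-type G1, OYE3, FLR1 and GRE2, of the oxidative stress response, were higher in replicate 2 in both fractions, by 5.49 and 3.86 for OYE3. Gaps between these G1 replicates correlated at 0.608 across 5162 genes, which are not independent replicates.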
